A study of Mus musculus with 2 samples.

How the data were processed

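ATAC-seq libraries were made, per the labels' protocols, from about 50000 sorted CD8+ T cells per culture with a Vazyme TruePrep kit and sequenced as paired reads of 150 bp on an Illumina HiSeq X instrument. There was 1 library for the culture with vehicle and 1 for the culture with TAMos. The submitters' processing notes name Trimmomatic 0.36, Bowtie2, MACS2 and the genome build mm10, without settings; read shifting, duplicate removal and the peak caller's options are not given in the sources used here. The deposited files are 1 peak list per library, called separately and not on pooled reads. Per the deposited values, each row holds an interval, a summit, a score equal to 10 times the −log10 q rounded down, a fold enrichment of the summit over local background (a ratio set by the authors' peak caller), a −log10 p and a −log10 q. The fold and −log10 q of a peak are the authors' own values and were used only to rank or filter peaks within a list, apart from the recovered coverage described below. The lists held 163215 rows for vehicle and 225656 rows for TAMo; rows with the same interval and several summits were counted as 1 peak. The narrowest interval was 150 bp and the lowest −log10 q was 1.32 in vehicle and 1.34 in TAMo, so weak regions depend on the calling threshold. Peaks lay on chromosomes 1 to 19; genes on the sex chromosomes were not analysed here.

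Before the data were examined, the following were fixed: the counts of peaks, overlap by at least 1 bp, strong one-library peaks (among the 50000 strongest by −log10 q of a list and overlapping no peak of the other full list), the promoter share, genes with a promoter peak in 1 library only, 21 gene lists and their statistic, and the rule for named genes. Genes, start sites and exons came from the GENCODE M21 basic annotation of the same assembly, with 20780 autosomal protein-coding genes. A peak was assigned to the nearest start site of a protein-coding gene within 100 kb of its summit, and promoters were 1 kb on either side of a start site. For each list, the median of log2((TAMo peaks + 0.5)/(vehicle peaks + 0.5)) was placed among 10000 random lists of the same size, matched on peak number in 10 bins. Of 377 list genes, 369 were found on chromosomes 1 to 19. Of the others, Foxp3, Cybb, Cd40lg, Cxcr3, Il2rg, Hprt and Pgk1 lie on chromosome X and Mx2 was not found in the gene table. Shares carry 95% Wilson intervals. Named genes were: up to 4 members per list with the largest difference between strong TAMo-only and strong vehicle-only peaks; the 8 genes with the strongest promoter peak in each library only; the genes nearest to the 8 strongest one-library peaks of each list; and 23 genes set beforehand, from Tcf7 to Itgam. After the first picks were seen, the promoter part of this rule was narrowed to promoter peaks that overlapped no peak of the other list, because the first picks were wide intervals that only touched the promoter window. Genes named beyond this rule are said to be chosen after their values were seen. Motif shares near summits, also planned, were not computed, as no genome sequence was used here.

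Read coverage was recovered after the lists had been seen, to allow a comparison at regions open in both libraries. The fold enrichment equals (coverage + 1)/(background + 1) and the −log10 p is a Poisson upper tail at that background, so both values together give the coverage at a summit. Solutions were taken as whole numbers of reads where the −log10 p matched within 1% of the step between neighbouring whole coverages, which left out 30 vehicle rows and 48 TAMo rows. The lowest background value was used at first; after it gave an isolated TAMo value, the most frequent background value, 4.71 reads in vehicle and 5.80 reads in TAMo, was taken as each library's depth in its place. Median summit coverage was 70 reads in vehicle and 83 reads in TAMo, with 10th percentiles of 23 reads and 26 reads. Log2 ratios of coverage were scaled by these backgrounds, with 95% exact binomial intervals from the reads at both summits. Overlapping intervals of both lists were joined into regions, and each gene's promoter was represented by its strongest peak in each library. These 2 peaks overlapped for 12924 of the 13554 genes with a ratio. The lists were also computed over those genes alone, and single ratios are printed only for them. A region was compared only if it had a peak in both lists, which keeps out the weakest sites. Random lists for promoter coverage were matched on promoter coverage. The balance of a list, its higher minus its lower genes per gene with overlapping peaks, was placed among random lists in the same way. Differences between distal and promoter medians carry bootstrap intervals over regions, which are not replicates. Reads are not independent molecules, so intervals cover counting error only, and no p-value was computed between the groups. Lists added later covered DNA replication, mitosis, ribosome biogenesis, mitochondrial ribosomes, further p53 targets, histone genes and ribosomal proteins. The comparison of background at the T cell receptor genes first used unpaired medians and was then changed to summits within 100 bp of each other. That change left the outcome the same. The outcome later went from argued against to open, when the ratio centred on the shared regions was added after its value was seen. A test of reads shared between histone gene copies was set aside to keep to 3 weighed patterns.

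On data simulated with the same formula the coverage was recovered at 100% of 20000 summits per library. Of 3000 strong peaks removed from a copy of the vehicle list, 2912 were found as one-list peaks, with 0 false ones, and 5000 of 5000 added peaks were found. Among lists of 25 genes given more peaks, 100% lay outside the central 95% of random lists, as did 3% of lists of 25 unchanged genes. For lists of 12 genes the shares were 100% and 1.5%. The simulated change per gene was larger than the list differences reported below, so sensitivity to differences of that size was not tested. The simulated gain was first a rounded value and was then set to the measured ratio of peak numbers, which redrew these shares. Alternatives covered the rows or intervals counted as peaks, a −log10 q of at least 5 or 10, overlap of at least 50%, equal numbers of peaks, the 20000 strongest peaks, a 500 bp gap, a 2.5 kb promoter, gene bodies extended by 10 kb, a pseudocount of 1, the net number of strong peaks and, added later, thinning of the TAMo coverage by the ratio of the background values. The thinning was first used to test depth as a cause of the longer TAMo list and was replaced by peak numbers at equal multiples of background, because it removed few peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.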

Results

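Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse OT-I CD8+ T cells, whose transgenic receptor recognises an ovalbumin peptide. The cells were cultured for 48 h with that peptide and either vehicle or TAMos, which the labels describe as CD11b+ Ly6G− Ly6C-high cells purified from spleens of mice bearing LLC (Lewis lung carcinoma) tumours. CD8+ T cells were then sorted, and about 50000 cells went into each library. There was 1 vehicle library and 1 TAMo library, so no difference described here has a replicate check, and every interval covers counting error only. The lists held peaks on chromosomes 1 to 19. Background read coverage, recovered from the peak values, was 4.71 reads in the vehicle library and 5.80 reads in the TAMo library, a depth ratio of 1.23.

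The first comparison asked how many open regions each culture showed and how many they shared. The TAMo list held 179414 peaks covering 65.6 Mb and the vehicle list held 127423 peaks covering 46.9 Mb, a ratio of 1.41 in peak number. A TAMo peak overlapped 87.5% of vehicle peaks (95% Wilson interval 87.3 to 87.7%), and a vehicle peak overlapped 60.5% of TAMo peaks (60.3 to 60.7%). With each list divided into 10 equal parts by strength, 99.98% of vehicle peaks and 99.4% of TAMo peaks were shared in the strongest part, whereas in the weakest part 64.9% of vehicle peaks and 20.5% of TAMo peaks were shared. Promoters, here the 1 kb on either side of a transcription start site of a protein-coding gene, held 17.6% of vehicle peaks (17.4 to 17.8%) and 13.7% of TAMo peaks (13.5 to 13.8%). With equal numbers of peaks taken from both lists, the shared shares were 77.8% of vehicle peaks and 74.3% of TAMo peaks.

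**Figure D1:**
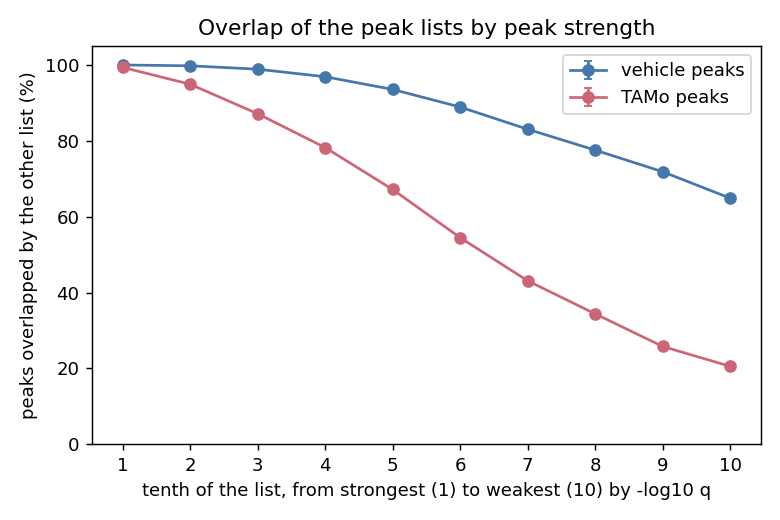
Share of peaks (%) overlapped by at least 1 bp of a peak in the other list, for 10 equal parts of the vehicle list (blue) and the TAMo list (red), ordered from the strongest to the weakest −log10 q, with 95% Wilson intervals. In the weakest part the share was 64.9% for vehicle peaks and 20.5% for TAMo peaks.

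Strong peaks found in 1 library only, like all peaks, were mostly in introns and between genes. Coverage of the other library was not measured at such sites, so a missing peak is a missing call and need not be a closed site. Among the 50000 strongest peaks of each list, 2705 TAMo peaks (5.41%, 5.22 to 5.61%) and 534 vehicle peaks (1.07%, 0.982 to 1.16%) overlapped no peak of the other list. The lists differ in length, which enters this contrast: with the TAMo list shortened to the length of the vehicle list, the vehicle-only count was 1049 against the same 2705. The cut at 50000 peaks also fell at unlike strengths. Among strong one-library peaks near list genes, the lowest −log10 q was 41.6 in vehicle (Ccr7) and 99.8 in TAMo (Ly6g). Of the 2705 TAMo-only peaks, 57.2% lay in introns, 34.3% between genes and 3.59% at promoters, against 48.9%, 32.5% and 13.7% of all TAMo peaks. For the 534 vehicle-only peaks these shares were 50.4%, 37.6% and 6.74%, against 46.6%, 30.8% and 17.6% of all vehicle peaks. By −log10 q, the strongest TAMo-only peak lay in an intron on chromosome 14 (103606867 to 103607475, mm10), 43121 bp from the start site of Slain1, with a summit coverage of 846 reads; a strong vehicle-only peak lay elsewhere near that gene (103661156 to 103661535, 153 reads). The strongest vehicle-only peak lay in an intron on chromosome 6 (108482326 to 108482969) with no protein-coding start site within 100 kb. Vehicle-only peaks also lay 9324 bp from Gfi1, a transcriptional repressor of lymphoid and myeloid development (chromosome 5, 107734980 to 107735270, 375 reads), and 82618 bp from Trib1 (chromosome 15, 59731107 to 59731477, 462 reads). Near Trib1 there was also a strong TAMo-only peak (59734441 to 59734721, 513 reads). The other nearest genes under the vehicle rule were 4930568D16Rik, Gucy2e and Lonrf2. Of the 8 strongest TAMo-only peaks, 6 carried an identical fold enrichment of 4.16 and −log10 q of 873, and no whole read coverage was recovered from these values. The interval near Alpl also held other summits, the highest of 42 reads. They are among 7 such summits on 6 chromosomes, with an implied background of 725 reads against 6.01 reads at neighbouring summits. Eif4a3, Dip2c, S100a11, Alpl and Akap13, the genes near them, are named only because the rule takes them. Without such peaks, a choice made after the values were seen, the next strongest TAMo-only peaks included those near Fam53b (703 reads), Impg2 (706 reads), Nat9 (939 reads) and Sec14l3 (572 reads).

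Promoter peaks were found for 13561 of 20780 autosomal protein-coding genes in both libraries, for a further 706 genes in the TAMo library only and for 180 in the vehicle library only. The strongest TAMo-only promoter peaks belonged to Sec14l3 (chromosome 11, 4064660 to 4065340, 572 reads), Cd300c, a myeloid surface receptor gene (chromosome 11, 114958795 to 114959524, 553 reads), and Psapl1 (chromosome 5, 36202836 to 36203168, 459 reads), followed by Olfr61, Klhl35, Orm3, Mmrn2 and Prelp. The strongest vehicle-only promoter peak belonged to the histone gene Hist1h3d (chromosome 13, 23575619 to 23575829, 482 reads), and others belonged to 2200002J24Rik, Padi3, Tomm20l, Ccdc106, Clec2i and Gm21969. Hist1h3d has near-identical copies, and whether reads were shared between them was not tested. Promoters named here had a strongest peak that overlapped no peak of the other list, a condition added after the first picks were seen.

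Regions open in both libraries were compared by summit coverage divided by each library's background coverage, a comparison added after the lists had been seen. Over 103845 shared regions the median log2 ratio of TAMo over vehicle was 0.28 (quartiles −0.12 and 0.89); it was 0.05 at 18712 promoter regions and 0.38 at 85133 distal regions. Coverage was at least 4-fold higher in the TAMo library at 5966 distal regions and at least 4-fold lower at 331. At promoters, 146 regions were at least 4-fold higher and 4 at least 4-fold lower. Because of the 0.28 shift, a promoter is called higher below only if its 95% interval lay above 0.28, and lower only if it lay below 0, so that the direction held with and without centring on the shared regions. The rule asks more of a higher call than of a lower one. Random lists thus leaned to lower calls, with a median balance of −0.08 for those matched to effector genes. Each library's strongest promoter peak was used, and for 630 of 13554 genes these did not overlap. Ratios of single genes and counts of higher and lower genes are given below only for overlapping peaks, a condition added after the values were seen.

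Among the genes fixed in advance, promoter coverage was higher in the TAMo library at Havcr2 (ENSMUSG00000020399), which encodes the inhibitory receptor TIM-3 (log2 ratio 0.95, 0.75 to 1.15). It was lower at Prf1 (ENSMUSG00000037202), which encodes the pore-forming protein perforin (−0.73, −0.89 to −0.57), at the inhibitory receptor genes Ctla4 (ENSMUSG00000026011; −0.64, −0.85 to −0.44) and Lag3 (−0.52, −0.69 to −0.35), and at Lef1, a transcription factor of naive and memory T cells (−0.47, −0.65 to −0.30). Lef1 also had a strong TAMo-only peak 857 bp from a start site (chromosome 3, 131109476 to 131109842, 437 reads). Ifng (−0.38), Nr4a1 (−0.23) and Gzmb (−0.13, −0.25 to −0.01) were also lower. Over all 13554 genes with a ratio the quartiles were −0.13 and 0.23, and 2399 had an interval below 0. The Gzmb value was thus ordinary for a promoter, at about the lower quartile. Neither call was made for Tcf7 (0.16), Prdm1 (0.28), Pdcd1 (0.07), Entpd1 (−0.00), Eomes (−0.03) and Spi1 (0.89, 0.18 to 1.63). The strongest promoter peaks of Il2, Il7r, Tox and Tbx21 lay at different sites in the 2 libraries, so no ratio is given. At Il2, the gene of a T cell growth factor, they were chromosome 3, 37125793 to 37125962 in vehicle and 37126054 to 37126271 in TAMo. A promoter ratio need not describe the whole locus. Over all shared regions assigned to a gene, the median departed from the promoter at Prf1 (0.42), Lef1 (0.26), Havcr2 (−0.16), Nr4a1 (0.10) and Entpd1 (1.09). It was below 0, as at the promoter, at Ctla4 (−0.33), Lag3 (−0.52), Ifng (−0.10) and Gzmb (−0.33). Foxp3 lies on chromosome X and was not analysed here.

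**Figure D2:**
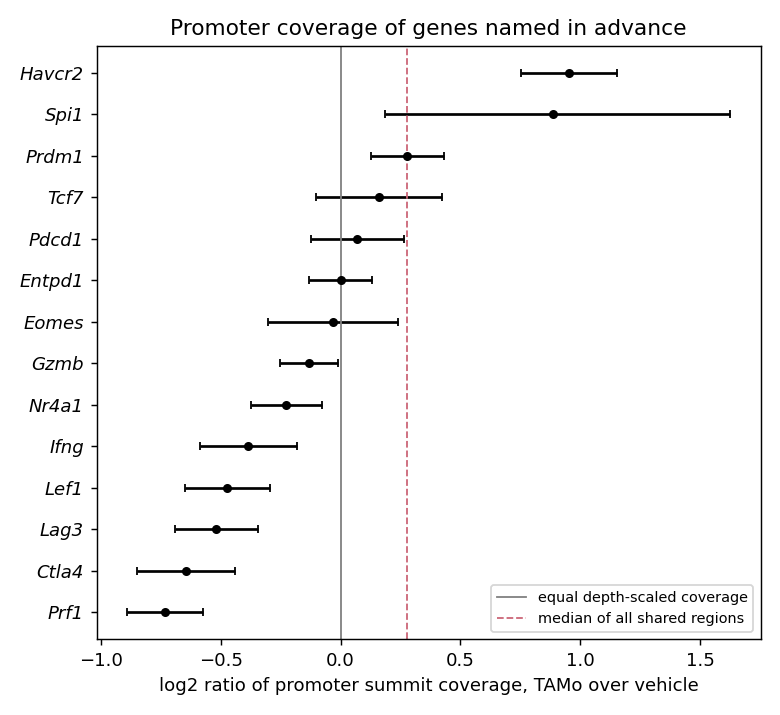
Log2 ratio of promoter summit coverage, TAMo over vehicle, scaled to background, for genes fixed in advance whose promoter peaks in both libraries overlapped and which are named in the text (points), with 95% exact binomial intervals for counting error; the dashed line is the median of all shared regions (0.28). The values ran from −0.73 for Prf1 to 0.95 for Havcr2.

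By peak number, the TAMo list gained fewer peaks near genes of activated and effector T cells than near random genes, but none of these results held under every measure. Peaks were assigned to the nearest start site within 100 kb, and each list's median log2 ratio of peak numbers was placed among 10000 random lists matched on peak number. The activation list of AP-1, NFAT and related genes had 705 TAMo and 655 vehicle peaks, a median of 0.08 against 0.38 in random lists (percentile 0.02). The inhibitory receptor and exhaustion list had a median of 0.14 (percentile 0.04), the effector list 0.09 (percentile 0.085) and the chemokine receptor and adhesion list 0.20 (percentile 0.77). These 4 of 20 lists lay outside the central 95%, where chance puts about 5% of lists. The percentiles describe these libraries. None of the 4 lists stayed outside in coverage of shared regions, where the percentiles were 29.8 for activation, 26.0 for inhibitory receptors and exhaustion, 10.3 for effector and 50.7 for chemokine receptors and adhesion. With equal numbers of peaks the activation (5.52), inhibitory (5.61) and chemokine (29.2) calls ended. Those for the effector (11.7) and inhibitory (2.73) lists ended with gene bodies extended by 10 kb, and those for activation (17.3), effector (5.27) and chemokine (89.0) by net strong peaks. Housekeeping genes were also low with extended gene bodies (percentile 0.14) and so were cytokine receptors (0.825).

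In the inhibitory receptor and exhaustion list, 6 strong peaks were vehicle-only and 1 was TAMo-only (percentile 0.07 for the net number per gene). Vehicle peaks counted as strong at a lower −log10 q than TAMo peaks. Random lists share that rule, but the raw counts are not at equal strength. Vehicle-only peaks lay near Ctla4 (chromosome 1, 60936314 to 60936683, 269 reads), Tigit (chromosome 16, 43702150 to 43702482, 212 reads), Tox (chromosome 4, 6986701 to 6986983, 194 reads) and Rbpj (294 reads), and the TAMo-only peak lay 98611 bp from Egr2 (121 reads). The vehicle-only peaks named lay 27279 bp (Ctla4), 38203 bp (Tigit), 3950 bp (Tox) and 60215 bp (Rbpj) from a start site. Near means within 100 kb throughout. Other peaks called near were almost as far as that of Egr2, such as those of Ifngr1 (98042 bp) and Egln3 (93939 bp). The cytokine receptor list had 5 vehicle-only and 4 TAMo-only peaks (percentile 1.66). Among them were vehicle-only peaks near Il7r and Ifngr1, a single TAMo-only peak near Il6ra, and both kinds near Tnfrsf1b. Other lists held more TAMo-only than vehicle-only peaks, within the central 95%: 10 against 1 in the TGF-β and regulatory T cell list, with 2 each near Pmepa1, Smad3 and Smad7 and 1 near Ldlrad4; 8 against 0 in the glycolysis and hypoxia list, with 2 each near Adm and Pfkp and 1 each near Hk2 and Egln3; and 12 against 1 in the apoptosis and p53 list, with 2 each near Gadd45a, Zmat3 and Cdkn1a and 1 near Cflar.

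The naive, memory and stem list had 10 TAMo-only and 8 vehicle-only strong peaks, with 3 vehicle-only peaks near Bach2, 3 TAMo-only and 1 vehicle-only near Klf2, and 1 TAMo-only each near Foxp1 and Satb1. Effector genes had 5 of each, with TAMo-only peaks near Prdm1, Fasl and Klrg1 and a vehicle-only peak near Gzmb. The activation list had 7 TAMo-only peaks, with 2 near Fos and 1 each near Nfatc2 and Myc, and 4 vehicle-only peaks, with 1 near Fosl2. Chemokine receptor and adhesion genes had 12 TAMo-only peaks, 3 of them near Itga4, an integrin subunit gene, and 1 each near Itgal, Ccr1 and Itgb1, against 3 vehicle-only. The 3 near Itga4 were neighbouring intervals (chromosome 2, between 79167177 and 79168541), 87354 to 88183 bp from a start site. They need not be 3 separate sites. The amino acid, arginine and stress list had 7 TAMo-only and 3 vehicle-only peaks, with TAMo-only peaks near Ass1, Nos2 and Slc7a11 and both kinds near Ddit4. The interferon list had TAMo-only peaks near Isg20, Mx1 and Usp18 and no vehicle-only peak.

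Median log2 ratios of peak numbers in the lists inside the central 95% were 0.26 for the naive, memory and stem list (percentile 4.07), 0.29 for the TGF-β and regulatory T cell list (13.6), 0.36 for interferon response (34.8), 0.24 for cytokine receptors (2.52) and 0.49 for glycolysis and hypoxia (76.9). The median was 0.30 for amino acid, arginine and stress genes (16.5). They were 0.20 for cell cycle (7), 0.31 for apoptosis and p53 (16.3) and 0.09 for housekeeping genes (5.67), of which Ywhaz and Eef1a1 had a strong TAMo-only peak each.

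Cell cycle genes had lower promoter coverage in the TAMo library. The list's median log2 ratio was −0.23 over 26 genes, against 0.01 in random lists matched on promoter coverage (percentile 0.00); 15 genes were lower and 2 higher. The lower genes included the replication helicase genes Mcm6 (−0.77, −0.92 to −0.62) and Mcm7 (−0.59, −0.73 to −0.45), the kinase gene Cdk2 (−0.61, −0.80 to −0.41) and the cyclin gene Ccne2 (−0.33, −0.47 to −0.19), all but Ccne2 picked after their values were seen. The higher genes were the D-type cyclin genes Ccnd1 (1.86, 1.51 to 2.23) and Ccnd2 (0.50, 0.35 to 0.66); Aurkb was at 0.00. Promoter coverage was higher than in random lists for chemokine receptor and adhesion genes (median 0.22, percentile 99.4, with 4 higher and 5 lower of 20) and for naive, memory and stem genes (0.16, percentile 98.6, with 2 higher and 4 lower of 22). The balance of higher and lower genes in these lists lay inside the central 95% of random lists (percentiles 61.9 and 63.5). Within the former, Ccr1 (1.24) and Itga4 (0.74) were higher and Itgb1 (−0.70) and Itgal (−0.31) lower; within the latter, Satb1 (0.72) was higher. The call for the naive, memory and stem list ended without the genes whose peaks did not overlap (percentile 90.8), with a 2.5 kb promoter window (66.1) and with unmatched random lists (96.6). All 3 results use the comparison added after the lists had been seen.

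**Figure D3:**
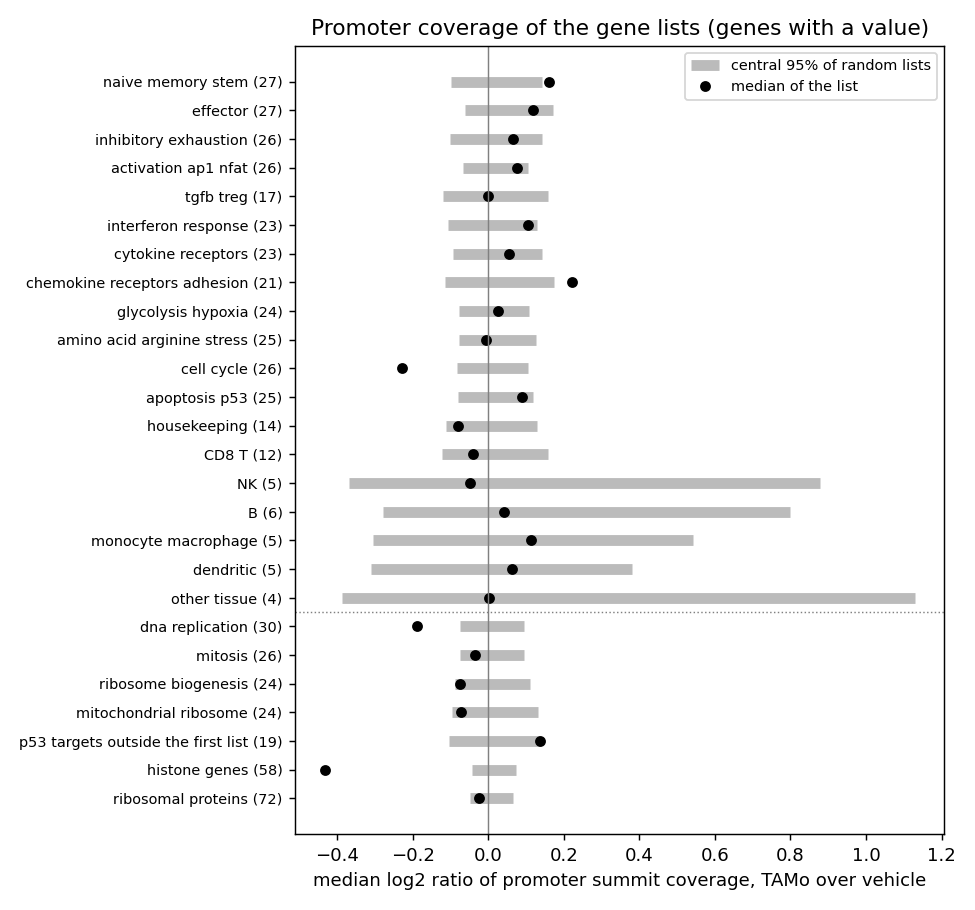
Median log2 ratio of promoter summit coverage, TAMo over vehicle, of each gene list (points, with the number of genes that had a value), against the central 95% of 10000 random lists matched on promoter coverage (grey bars); lists under the dotted line were added later. The cell cycle list lies at −0.23 and the histone genes at −0.43, both below their bars.

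The remaining lists lay inside the central 95% for promoter coverage, with medians of 0.12 for effector genes, 0.07 for inhibitory receptor and exhaustion genes, 0.08 for activation genes, 0.00 for TGF-β and regulatory T cell genes, and 0.11 for interferon response. The medians were 0.06 for cytokine receptors, 0.03 for glycolysis and hypoxia, −0.00 for amino acid, arginine and stress genes, 0.09 for apoptosis and p53 genes and −0.08 for housekeeping genes. Medians hid members in both directions. Of 24 inhibitory receptor and exhaustion genes 8 were higher and 7 lower, a balance at percentile 91.2 of random lists. Of 21 apoptosis and p53 genes 6 were higher and 3 lower, a balance above the central 95% (percentile 99.7). So was that of interferon genes, with 4 higher and 1 lower of 20 (99.9). Of 25 effector genes 3 were higher and 5 lower, a balance equal to the median of random lists (−0.08, percentile 44.6). Among the higher ones was Klrg1, a receptor of terminal effector cells (2.31, 1.71 to 2.97), with only 26 reads in vehicle.

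Markers of CD8 T cells had promoter peaks in both libraries, and so did some markers of other cell types. All 12 CD8 T cell markers had a promoter peak in both libraries, at a median of 115 times background in vehicle and 117 times in TAMo; their peak number ratio was 0.18 (percentile 3), and their strong one-library peaks were 3 in each library. Promoter coverage was lower at Thy1 (−0.75), Zap70 (−0.44) and Cd3g (−0.15) and higher at Cd8b1 (0.45), all under both scalings, while Runx3 was at 0.01. Of 15 monocyte and macrophage markers 6 had a promoter peak in vehicle and 8 in TAMo. Csf1r, the receptor gene for macrophage colony-stimulating factor, had 4 peaks in vehicle and 17 in TAMo, with a promoter peak in TAMo only at 17.2 times background. Itgam, which encodes CD11b, had a promoter peak in TAMo only at 20.3 times background. Promoter coverage at Cd14 was 30.0 times background in vehicle and 70.8 times in TAMo (log2 ratio 1.24, 0.96 to 1.53). Adgre1 had 5 peaks in vehicle and 13 in TAMo, with a TAMo-only promoter peak at 5.34 times background, and Fcgr1 had a vehicle-only one at 3.82 times. Spi1 was at 5.31 times background in vehicle and 9.82 times in TAMo, and Lyz2 had 0 peaks in vehicle and 2 in TAMo, with no promoter peak in either. As a list, monocyte and macrophage markers had a peak number ratio of 0.28 (percentile 25.2) and 2 strong TAMo-only peaks, near Csf1r and Cebpb. The ratio was 0.79 for neutrophil markers (percentile 93.2; Ly6g had a TAMo-only peak), 0.48 for dendritic cell markers (65.9; Flt3), 0.63 for B cell markers (84.1), 0.24 for NK cell markers (22.1) and 0.65 for markers of other tissues (88.0; Gata4, Ins2 and Apoa1). In coverage of shared regions, the lists of dendritic cell (median 0.87, percentile 99.5), NK cell (0.87, 99.4) and other tissue markers (0.77, 98.7) lay above the central 95%. Those of neutrophil (0.70, 94.3), monocyte and macrophage (0.48, 90.9), B cell (0.56, 90.5) and CD8 T cell markers (0.03, 13.3) lay inside it, and the cell cycle list lay below it (−0.14, percentile 0.00). The CD4 T cell list had 2 measured genes and was not placed among random lists.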

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

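Thinning of the TAMo coverage by the ratio of the background values, coverage at shared regions, promoter coverage with its own alternatives, and the list of strongest peaks without unrecovered summits were chosen after the data were seen; the other alternatives were planned. Vehicle peaks overlapped by TAMo peaks went from 87.5% to 86.3% when at least 50% of the peak had to be covered, 73.9% with 50% of both peaks, 88.2% and 90.3% with a −log10 q of at least 5 and 10, and 77.8% with equal numbers of peaks; TAMo peaks went from 60.5% to 56.8%, 52.5%, 60.8%, 59.6% and 74.3%. The 534 strong vehicle-only peaks became 12 among the 20000 strongest, 15896 among all peaks, 346 with a 500 bp gap, 1011 with 50% coverage and, added after the data were seen, 1049 with equal numbers of peaks; the 2705 TAMo-only peaks became 167 among the 20000 strongest, 70854 among all and 5270 with 50% coverage. TAMo-only peaks outnumbered vehicle-only ones in each. Promoter shares of 17.6% (vehicle) and 13.7% (TAMo) became 22.3% and 18.1% with a 2.5 kb window, and 21.7% and 17.5% with start sites of any gene; the TAMo share was 16.2% with equal numbers of peaks. These moves follow from what each alternative counts. The 4 lists outside the central 95% became 1 with equal numbers of peaks and 2 by net strong peaks. The chemokine receptor and adhesion list turned from −0.19 to 0.16 by net strong peaks and to 0.00195 in coverage of shared regions; the cause was not tested for either change in the lists. Of the other list results, 100 by peak numbers kept their side of the limits, 8 passed only under the alternative (cytokine receptors in 3, housekeeping genes with extended gene bodies, and cell cycle, NK, dendritic and other tissue lists in coverage of shared regions) and 10 no longer passed; by promoter coverage these were 52, 1 and 3. The 1 was the inhibitory receptor and exhaustion list with a 2.5 kb window (percentile 99.6). Peak totals and promoter genes found in 1 library stayed within 1.5 times; thinning left 178589 of 179414 TAMo peaks, too small a move to test stability, and is left out of the list counts. No paired analysis was possible because there was 1 library per group. Motif alternatives were not run. Depth limits weak sites: the lowest summits had 13 reads in vehicle and 14 reads in TAMo.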

Other observations

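The lists of replication, mitosis, ribosome and p53 target genes and the restriction to overlapping peaks were chosen after the data were seen. The tests of peak numbers at equal height, of distal against promoter regions, of T cell receptor genes, of the size of a housekeeping loss and of the balance of higher and lower genes were chosen only after their results were seen. Genes and regions in the first 2 paragraphs were also chosen after their values were seen.

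Histone gene promoters had a median log2 ratio of −0.43 over 58 genes (percentile 0.00 of random lists), and 43 of the 57 whose peaks overlapped were lower and 0 higher. Some share a peak, and sharing of reads between near-identical copies was not tested; over the 41 distinct vehicle peaks the median was also −0.43. Next to the histone cluster on chromosome 13, shared regions assigned to Gpx5 and Zfp184 had medians of −1.70 and −1.41, and each gene had 3 strong vehicle-only peaks. A copy of the ribosomal RNA gene on chromosome 17 (39843148 to 39846733) had 8530 reads in vehicle and 3891 reads in TAMo (log2 ratio −1.43, −1.49 to −1.38); the sequence has many copies in the genome. Promoters of ribosome biogenesis genes (−0.08, percentile 4.20) and of ribosomal proteins (−0.02, percentile 13.4) stayed inside the central 95%.

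Among shared regions with a mean coverage of at least 20 times background, the largest differences lay away from promoters. A region 27709 bp from the start site of Ctla4, an inhibitory receptor gene (chromosome 1, 60881121 to 60881554), had 319 reads in vehicle and 39 reads in TAMo (log2 ratio −3.33, −3.85 to −2.85), and 1 near Itsn1 had 576 reads and 58 reads (−3.61). Regions near Faap20 (4.97), Sulf2 (4.92) and Frmd4a (4.90) had the highest ratios among these. Samd4 had 8 strong TAMo-only peaks, and Stat4, which encodes a transcription factor of IL-12 signalling, had 4 strong vehicle-only peaks. At Itgax, the gene of CD11c, promoter coverage was higher in TAMo (1.84, 1.58 to 2.10).

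A difference in depth is argued against as the whole cause of the longer TAMo list, with background as the measure of depth: at or above 5 to 40 times background the ratio of TAMo to vehicle peaks was between 1.34 and 1.37, and at or above 100 times it was 1.27 (95% exact interval 1.24 to 1.31). A gain of the same size at every region is also argued against: at 40 to 80 times background the distal median exceeded the promoter median by 0.31 (95% bootstrap interval 0.29 to 0.33). The excess was 0.10 at 5 to 10 times, 0.31 at 10 to 20 times, 0.33 at 20 to 40 times and 0.19 at 80 to 160 times. A higher share of TAMo reads in open regions is consistent with the median of 0.28 at shared regions. With 1 library per group, a difference in library preparation remains open beside an effect of the co-culture.

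Peaks found in TAMo only might come from DNA of TAMos left after sorting, and CD8+ T cell sorting is the gate that should remove those cells. The monocyte and macrophage list lay at percentile 66.5 for net strong peaks, so a small share of TAMo DNA cannot be told apart from a change in the T cells: the list has few strong peaks and TAMo chromatin was not analysed here. Csf1r (17.2 times background), Itgam (20.3 times) and Adgre1 (5.34 times) had promoter peaks in TAMo only and Cd14 was higher (1.24), while Fcgr1 had one in vehicle only and Lyz2 had none. Outside that list, Cd300c had a TAMo-only promoter peak of 553 reads and the dendritic cell marker Itgax was higher (1.84), both picked for high values. Of 5 dendritic cell markers with a ratio, 1 was higher and 0 lower. In coverage of shared regions the monocyte list lay at percentile 90.9, and lists of dendritic cells (99.5), NK cells (99.4) and other tissues (98.7) lay higher. A share large enough to lower T cell DNA by 10% also stays open: background at Trac, Trbc1 and Trbc2 was at least 1.02 times that of vehicle by the median, but down to 0.84 times after centring on the shared regions. In vehicle this local background was 33.0 to 49.6 times that of the library, so it need not follow the share of T cell DNA.

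Cell cycle promoters had lower coverage in TAMo; fewer cycling cells is a hypothesis for it, and replication genes outside that list were lower too, as it needs (median −0.19, percentile 0.00 for the DNA replication list; Tk1 −1.75, Prim1 −0.97). By the bound set beforehand mitosis genes would argue against it for cycling as a whole (median −0.04, percentile 15.1), but they cannot decide the question. Sensitivity to a small shift in promoter coverage was not tested. Of the 26 mitosis genes, 17 had a ratio below 0. Their balance of 9 lower and 0 higher lay on the lower limit for matched random lists (percentile 2.17). That of the 69 ribosomal protein genes, 18 lower and 1 higher, lay at percentile 5.25. An equal loss at strong housekeeping promoters is argued against for ribosomal proteins (−0.02, percentile 13.4; cell cycle minus that list −0.20, 95% bootstrap interval −0.29 to −0.04), and random lists were matched on promoter coverage. It cannot be told apart for housekeeping genes (−0.08, percentile 7.67; difference −0.15, −0.23 to 0.02), since intervals for those and both other ribosome lists reach 0, and mitochondrial ribosome genes lay between the limits (−0.07, percentile 6.06; 2.12 without genes whose peaks did not overlap). A stronger p53 response may contribute: further p53 targets had a median of 0.14 (Phlda3 1.86, Zfp365 1.78), the first p53 list lay at percentile 92.4 (Mdm2 0.99 and Bax 0.87, but Gadd45a −0.20), and their balances of 6 higher and 0 lower of 18 and 6 higher and 3 lower of 21 lay at percentiles 100 and 99.7 (interferon genes, with 4 and 1 of 20, at 99.9), but the percentile of 97.495 for the further targets (96.5 where peaks overlapped) lay under the limit set beforehand, which keeps it open.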
